A study of Mus musculus with 4 samples.

How the data were processed

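RNA from RAW264.7 macrophages was sequenced before and after 2, 4 and 6 h of actinomycin D, with 1 library at each time and 4 libraries in all. Samples were placed on the time axis by the treatment given in their labels. Per the labels' protocols, ribosomal RNA was depleted and libraries were prepared with a directional kit. Reads were handled with STAR 2.5.3a, featureCounts and Subread 1.6.3 on the mm10 build, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that fit several places are not given in the sources used here.

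One deposited table of 41324 genes held the measurements. Its raw counts per gene, per the file headers, were whole numbers and were used as deposited. Its normalized signal columns had been made by the authors by dividing each library's counts by 1 whole number per library, as recomputation showed, and the origin of these divisors is not given in the sources used here. Relative to the untreated library the divisors were 1.73, 3.44 and 0.575 at 2, 4 and 6 h, against effective library sizes after TMM of 1.42, 2.49 and 0.402. The half-life and fit columns of the authors' deposited table were taken as a score and compared with fits of the same normalized values. Columns not matched to a sample numbered 0.

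Total counts were 35669434, 38260540, 70289647 and 12762100 at 0, 2, 4 and 6 h, so the 6 h library carried the largest counting error. Shares of counts and levels of named genes were given with exact binomial 95% intervals, and a count of 0 was taken to allow up to 3 counts. These intervals cover counting error only.

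Trends were fitted with edgeR 4.0.16 in R 4.3.3, using TMM factors, genes with a mean CPM (counts scaled to a common library total) of at least 1 over the 4 libraries, and the quasi-likelihood test of a slope in log2 per h, with 2 residual degrees of freedom. Genes fell or rose where the Benjamini-Hochberg adjusted p was under 0.05. Bends were tested as the quadratic time term, with 1 residual degree of freedom. Changes from the untreated library used log2 CPM with a prior count of 0.5. Apparent half-lives were −1 divided by the slope after subtracting the median slope of the ribosomal protein list.

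Gene lists, 29 in all, were fixed before the data were examined, as were the tests, their alternatives and the rule for named genes. The lists held immediate-early genes, signalling feedback regulators, cytokines and chemokines, NF-kB pathway members, interferon genes, p53 targets, apoptosis regulators, mitotic genes, G1/S genes, ribosomal proteins, translation factors, nuclear respiratory chain genes, mitochondrially encoded proteins, glycolysis, proteasome, macrophage identity genes, lysosome, endoplasmic reticulum secretory genes, stress response, heat shock, cholesterol metabolism, circadian clock, RNA decay, snoRNA host genes, nuclear long non-coding RNAs, structural small RNAs, markers of other cell types, replication-dependent histones and numbered Zfp genes. A list's median slope was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart outside the central 95%. These random lists were drawn from all tested genes, list members included. Such percentiles describe these libraries, since genes are not replicates.

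The rule for named genes took the 12 steepest falls and the 8 steepest rises past the test with a mean CPM of at least 10, the same direction at each step and names other than predicted models, clones and pseudogenes. It also took the 3 most abundant members of each list and its steepest falling member at a mean CPM of at least 5, 9 benchmark genes, and the 5 largest bends. Some genes that the rule takes, or that passed a test within a list, are not reported here.

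Untranslated regions came from GENCODE annotation of the mm10 build, to which 9961 of 10837 tested symbols were matched (91.9%), 9818 of them by the same symbol and the others through older names. Of these, 9657 had an annotated 3' UTR. Motif lists were matched on expression and 3' UTR length in 10 bins each. Their matched lists were drawn from all genes with a 3' UTR, motif genes included. Coordinates are 1-based.

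The fits were tested on simulated data with the means and sizes of the 4 libraries and a dispersion of 0.02. Of 200 genes given a slope of 0.25 log2 per h, 184 were recovered with 9 false calls, and of 200 with a slope of 0.5, 200 were recovered with 15 false calls. Of 200 genes that dropped by 2 log2 before 2 h and then stayed level, the bend test recovered 137 with 11 false calls, and the straight line 107. In these simulations all other genes were flat, so errors from the TMM scaling were not tested, nor were slopes weaker than 0.25. Of 100 simulated lists of 28 genes shifted by −0.1 log2 per h, 95 lay below percentile 2.5, and of 100 unshifted lists 4 lay outside the central range.

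Alternatives fixed before the data were examined were DESeq2 size factors, total counts, scaling on ribosomal protein or respiratory chain mRNAs, no filter or a mean CPM of at least 5, the DESeq2 1.42.0 Wald test, limma-trend (limma 3.58.1), robust and legacy edgeR fits, other anchors and times for half-lives, a prior count of 2, the ATTTA pentamer, and each library left out in turn. Scaling on the deposited divisors, total counts without the 4 genes with over 2% of the counts of a library (RP23-81C12.1, RP23-81C12.3, mt-Rnr1 and mt-Rnr2), the joint test of slope and bend, the through-origin half-lives and the further 3' UTR measures were chosen after seeing the data. Genes with 0 counts in all libraries, 22690 in number, and genes under the filter entered no test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for sequence features, tests and plots.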

Results

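RAW264.7 cells, a mouse macrophage line, were treated with 10 µg/ml actinomycin D, a drug that binds DNA and blocks transcription, so that the loss of each RNA could be followed over time. RNA was sequenced before treatment and after 2, 4 and 6 h, with 1 library at each time, and the course was made to measure mRNA half-lives across the transcriptome. The labels name the material as cytoplasmic RNA, ribosomal RNA was depleted, and the library kit keeps the strand of each transcript. The untreated library held 35669434 gene counts, the 2 h library 38260540, the 4 h library 70289647 and the 6 h library 12762100. Counts above 0 were present for 15930, 16489, 17418 and 14954 genes in the same order. With 1 library per time there was no replicate check of any time point, and the labels do not say whether the times came from separate cultures. Trend p-values therefore measured only the spread of these 4 libraries around a straight line, and bend and joint p-values that around a curve. In each, edgeR shares information on spread across genes, so they do not rest on the values of a single gene alone. All intervals on counts covered counting error only.

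A single clone-named gene, RP23-81C12.1, took 23.1% of the untreated counts (exact binomial 95% interval 23.1 to 23.2%) and 0.386% of the 2 h counts (0.384 to 0.388%). The mitochondrial large ribosomal RNA mt-Rnr2 took 1.44% of the untreated counts (exact binomial interval 1.437 to 1.444%) and 11.9% of the 6 h counts (11.84 to 11.87%). Such shares change with every other gene in the library, so slopes were computed after TMM scaling, which sets the typical gene to a slope near 0. A slope above 0 thus describes a transcript that lost less than the typical gene, lost none or gained, and these were not told apart. List members named in the text because they passed or missed a test, beyond the fixed rule for named genes, were chosen after their values were seen.

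Shut-off separated histone, immediate-early, NF-kB, signalling-feedback and zinc-finger mRNAs, which lay on the falling side, from lysosomal, endoplasmic reticulum and respiratory chain mRNAs, which lay on the slow side. Of 10837 genes tested with edgeR, 1859 fell and 935 rose along the 6 h at an adjusted p under 0.05, so that 66.5% of calls were falls, and 5128 genes had an unadjusted p under 0.05. The share of falls depended on the scaling of the libraries. It was 86.7% with total counts (1350 fell, 207 rose) and 86.4% with total counts lacking the 4 genes RP23-81C12.1, RP23-81C12.3, mt-Rnr1 and mt-Rnr2 (2116 and 334). Scaling on ribosomal protein mRNAs gave 95.2% (2597 and 131), scaling on nuclear respiratory chain mRNAs 96.1% (1516 and 61), and the divisors behind the deposited normalized values 98.5% (5039 and 78). Relative to TMM, these scalings moved the median gene over 6 h by 0.13 log2 (total counts), −0.35 (ribosomal proteins), −0.33 (respiratory chain) and −0.52 (deposited divisors). Without the 4 h library 351 genes fell and 25 rose, and without the 2 h library 1964 fell and 448 rose. Of 63 genes named by the fixed rule and past the test, 33 also passed in the same direction without the 4 h library, against 57, 56 and 56 without the 0, 2 and 6 h libraries. Among the genes named here, those that then missed the test without the 4 h library included Snora23, mt-Rnr2, B2m, Btg1, Atf3, Spred1, Spred2, Skil, Ccl4, Irf5, Ei24, Eif3a, Atp5g3, mt-Cytb, Hk2, Psmd7, Lyz2, Ctsb, Edem1, Fasn, Csnk1d, Clock, Snhg1, Snhg17, Neat1, Kcnq1ot1, Zfp106 and Zfp143. Skil and Atp5g3 also missed it without the untreated library, and Psmd7, Snhg1 and Snhg17 without the 2 or the 6 h library.

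Replication-dependent histone mRNAs, which serve the packaging of newly made DNA and end in a stem-loop in place of a poly(A) tail, fell together. Of 54 measured histone genes 53 fell (53 fell and 1 rose adjusted over the list alone), and the 12 steepest falls picked by the fixed rule were all histone genes. The median histone change from the untreated library was −2.53 log2 at 2 h, −4.07 at 4 h and −4.93 at 6 h. The core histone gene Hist1h3h had the steepest slope, −1.33 ± 0.093 log2 per h (SE, edgeR adjusted p = 0.0145), and stood at 8.92%, 2.05% and 0.538% of the untreated level at 2, 4 and 6 h (counting interval at 6 h 0.111 to 1.58%, from 3 counts against 1387). Annotation of the mm10 build places it on chromosome 13, from 21717659 to 21718069 on the plus strand. The linker histone gene Hist1h1d had a slope of −0.99 (adjusted p = 0.0245), and the abundant Hist1h4d and Hist1h1c stood at 7.61% and 5.95% of untreated at 6 h. Hist2h2be, the remaining histone gene, had a slope of 0.10 (adjusted p = 0.0655).

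The histone list had a median slope of −0.84 log2 per h, below all 10000 expression-matched random lists, whose median was −0.0097. Between 49 and 53 members fell under all 7 scalings, and 48 fell without the 4 h library. Histone genes are near-identical copies of one another, and how the authors' counting treated reads that fit several copies is not given in the sources used here, so the values of single members are uncertain.

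Among cell-cycle mRNAs, Cdt1, which licenses replication origins, had a slope of −0.46 ± 0.04 log2 per h (edgeR adjusted p = 0.0151) and stood at 14.9% of untreated at 6 h. The F-box cyclin Ccnf stood at 16.4% (slope −0.44, adjusted p = 0.0206), and the mitotic kinases Aurka and Plk1 had slopes of −0.38 and −0.27 (both adjusted p = 0.0145). Of 43 measured G1/S and replication genes 12 fell and 2 rose (15 and 4 adjusted over the list alone); the 2 that rose were Cdk6 and Ccnd2, partners in G1 progression. Of 37 mitotic genes 13 fell and 3, Hmmr, Cenpa and Bub1, rose (13 and 4 adjusted over the list alone). The proliferation marker Mki67 was at 127% of untreated at 6 h (adjusted p = 0.0783) and the helicase subunit Mcm5 at 95.4% (adjusted p = 0.597). Median slopes of −0.016 for the G1/S list (percentile 0.270 among matched lists) and −0.019 for the mitotic list (percentile 0.030) turned to 0.0052 and 0.0026 with total counts, under which 9 G1/S and 3 mitotic genes fell and 0 rose. The deposited divisors gave 35 G1/S and 28 mitotic falls and 0 rises. The G1/S percentile was 3.76 from 0 to 2 h alone and 5 without the 6 h library, without the untreated library the mitotic percentile was 5.04, and without the 4 h library 4 G1/S and 3 mitotic genes fell. Mitotic falls numbered 7 without the 2 h library. Mitotic rises numbered 1, 1, 0 and 5 and G1/S rises 3, 2, 0 and 6 without the 0, 2, 4 and 6 h library.

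**Figure D1:**
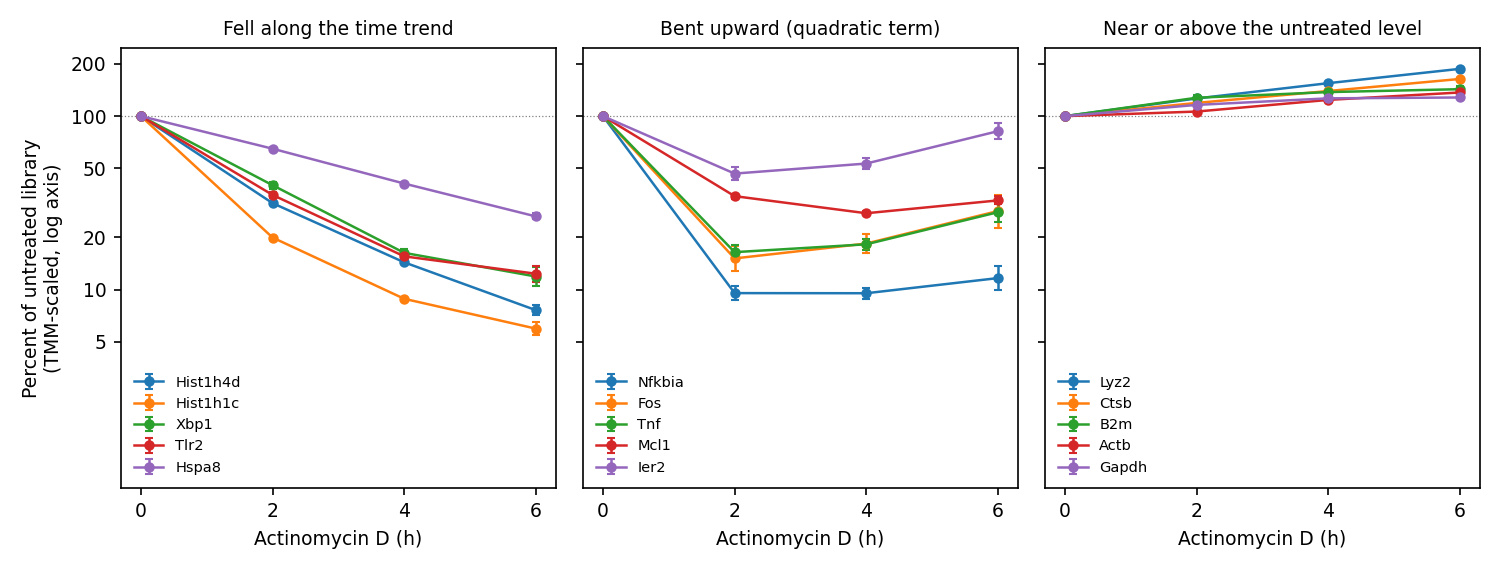
Level of 15 named mRNAs at 0, 2, 4 and 6 h of actinomycin D, in percent of the untreated library on a log axis, after TMM scaling, with 1 library per time and error bars that are 95% counting intervals. Histone Hist1h4d reached 7.61% at 6 h, Fos was lower at 2 h (15.1%) than at 6 h (28.4%), and Lyz2 reached 187%; Gapdh and B2m had slopes above 0 with TMM and below 0 with the deposited divisors.

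The immediate-early transcription factor Fos, whose mRNA is a standard of rapid decay, stood at 15.1% of untreated at 2 h, 18.4% at 4 h and 28.4% at 6 h (counting interval at 6 h 22.8 to 35.0%). The cytokine Tnf followed the same shape with 16.4%, 18.2% and 27.9%, and the immediate-early gene Ier2 stood at 46.6%, 53.3% and 81.9%. None of these 3 passed the straight-line test (edgeR adjusted p = 0.196, 0.178 and 0.72), and all 3 passed the test of a bend (adjusted p = 0.0015, 0.00066 and 0.00031). Without the untreated library their slopes were 0.22, 0.19 and 0.20 log2 per h, each past the line test as a rise. Without the 2 h library Tnf passed the line test as a fall (−0.34, edgeR adjusted p = 0.0446). The survival factor Mcl1 stood at 34.6%, 27.5% and 32.7% (adjusted p = 0.081), and passed without the 2 h library (adjusted p = 0.0253) or the 6 h library (0.027). The cell-cycle inhibitor Cdkn1a stood at 65.9%, 59.5% and 62.3% (adjusted p = 0.0833), and passed without the 2 h (0.0462) or the 6 h library (0.0336). Fos lies on chromosome 12 from 85473890 to 85477273 on the plus strand, and Tnf on chromosome 17 from 35199381 to 35202007 on the minus strand. Myc lay under the abundance filter.

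Of the housekeeping genes, the antigen-presentation subunit B2m rose with TMM (slope 0.08, adjusted p = 0.048) and had a slope of −0.0040 with the deposited divisors. The glycolytic enzyme Gapdh stood at 116%, 127% and 128% of untreated (adjusted p = 0.0594; slope −0.027 with the deposited divisors), and the cytoskeletal Actb at 106%, 124% and 137% (adjusted p = 0.105). B2m missed the test without the untreated (adjusted p = 0.155) or the 4 h library (0.14), and Gapdh passed it without the 6 h library (0.0396).

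Immediate-early genes, the transcription factors and growth-response genes that cells induce within minutes, lay low from 2 h on, with median changes of −1.60, −1.71 and −1.27 log2 at 2, 4 and 6 h. The stress-induced factor Atf3 fell to 14.2% of untreated (slope −0.48 ± 0.09, edgeR adjusted p = 0.0338), and the antiproliferative gene Btg1 to 15.6% (−0.45 ± 0.10, adjusted p = 0.0419). Klf4 and Jund, 2 further transcription factors, also fell (adjusted p = 0.0441 and 0.0352), whereas Fosb, at a mean CPM of 1.12, rose (0.30, adjusted p = 0.0321). Of 28 measured members 4 fell and 1 rose on the straight line (2 and 1 adjusted over the list alone), with 16 falls under total counts and 0 under respiratory chain scaling. With TMM 1859 of all 10837 genes fell on the straight line and 935 rose, so the list's share of falls was not above that of all genes. A joint test of slope and bend, added after the values were seen, gave 26 lower and 1 higher. Among all 10837 genes that test gave 3994 lower and 3554 higher. The list's median slope of −0.21 lay at percentile 0.010 of matched lists. The sign turned without the untreated library (0.084 above matched lists, percentile 100), with 4 members falling and 8 rising. Falls numbered 12 without the 2 h library, 0 without the 4 h and 12 without the 6 h library.

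Feedback regulators of signalling, which cells induce to shut off kinase and cytokine pathways, had median changes of −1.41, −1.49 and −1.08 log2. The differentiation inhibitor Id3 fell (slope −0.32, edgeR adjusted p = 0.0347), as did the TGF-beta antagonists Smad6 and Skil and the kinase inhibitors Spred1 and Spred2 (Spred1 to 63.9% of untreated, adjusted p = 0.0216). Of 22 measured members 5 fell and 0 rose (4 and 0 adjusted over the list alone), and the median slope of −0.18 lay at percentile 0.060. Signalling falls numbered 11 with total counts and 1 with respiratory chain scaling. Of 21 NF-kB pathway members 9 fell and 0 rose (13 and 0 adjusted over the list alone), with 4 falls under respiratory chain scaling and 15 under the deposited divisors. The falls included the signal adaptors Traf1 and Traf2 (slopes −0.32 and −0.40), the inhibitor of apoptosis Birc3 (−0.30) and the transcription factor subunits Rel, Rela and Relb (−0.17, −0.17 and −0.15). The NF-kB inhibitor Nfkbia, on chromosome 12 from 55489410 to 55492647 on the minus strand, stood at 9.54%, 9.52% and 11.6% of untreated (adjusted p = 0.0878), while Nfkb1, the precursor of the p50 subunit, stood at 102% at 6 h. The NF-kB list had a median slope of −0.17 (percentile 0.145). Without the untreated library the signalling list turned to 0.051 above matched lists (percentile 98.7) and the NF-kB list lay at percentile 3.24. Falls in the signalling list numbered 3, 11, 0 and 9 without the 0, 2, 4 and 6 h library in turn, and in the NF-kB list 6, 10, 0 and 13. Members that rose without the untreated library numbered 5 in the signalling and 3 in the NF-kB list.

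Cytokines and chemokines moved apart. The chemokine Ccl4 fell to 19.2% of untreated (slope −0.41 ± 0.10, edgeR adjusted p = 0.0462), whereas the secreted phosphoprotein Spp1, made in quantity by macrophages, rose to 301% (0.27 ± 0.04, adjusted p = 0.0213), as did the chemokine Ccl9 (0.21, adjusted p = 0.018). Spp1 lies on chromosome 5 from 104435118 to 104441050 on the plus strand. Of 14 measured members 1 fell and 2 rose (2 and 4 adjusted over the list alone), falls numbered 4 with total counts, rises 0 with ribosomal protein scaling, and the median slope of 0.025 lay at percentile 78.4 and turned to −0.062 with the deposited divisors. From 0 to 2 h alone the list differed from matched lists by −0.56 log2 (percentile 0.330), its median change at 2 h was −0.54, and 11 of 14 members bent upward. Without the untreated library the list lay 0.19 above matched lists (percentile 100) and 9 members rose, and Ccl4 missed the test without the untreated or the 4 h library. Cytokine falls numbered 4 without the 2 h and 3 without the 6 h library.

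The numbered Zfp genes, mostly repressors with zinc fingers and a KRAB domain, lay on the falling side as a list, the largest of the 29 by members. Zfp143, an activator of transcription, fell to 15.8% of untreated (slope −0.45 ± 0.06, edgeR adjusted p = 0.0225). The 2 that rose included the abundant Zfp106 (0.07, adjusted p = 0.0469), which had a slope of −0.020 with the deposited divisors and missed the test without the 0, 2 or 4 h library (adjusted p = 0.217, 0.087 and 0.169). Of 234 measured members 43 fell and 2 rose (10 and 1 adjusted over the list alone). Among all 10837 genes 1859 fell and 935 rose, so the share of falls in the list was close to that of all genes. The joint test gave 199 lower and 4 higher, against 3994 lower and 3554 higher among all 10837 genes. Falls numbered 87 with total counts, 92 with the deposited divisors and 18 with respiratory chain scaling. Median changes were −0.89, −1.09 and −0.91 log2 at 2, 4 and 6 h, and the median slope of −0.16 lay below all matched lists. It lay at percentile 46.4 without the untreated library, with 28 falling and 12 rising. Without the 4 h library 0 members passed by edgeR, and without the 2 or the 6 h library 82 and 95 fell.

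Among p53 targets, the metabolic regulator Tigar fell to 21.1% of untreated (slope −0.38 ± 0.03, edgeR adjusted p = 0.0147) and the repair gene Xpc had a slope of −0.30 (adjusted p = 0.0162). The pro-apoptotic Bax was at 114% (adjusted p = 0.162), and Ei24, an endoplasmic reticulum protein, rose (0.09, adjusted p = 0.037; it did not pass without the untreated or the 4 h library, or with the deposited divisors, adjusted p = 0.977). Of 20 measured p53 targets 4 fell and 1 rose (7 and 3 adjusted over the list alone), with a median slope of −0.10 (percentile 2.01), and 10 fell and 0 rose with the deposited divisors. That percentile was 6.80 at a mean CPM of at least 5 and 47.5 without the untreated library, and falls numbered 9, 1 and 9 and rises 2, 0 and 2 without the 2, 4 and 6 h library.

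Clock genes gave 3 falls, Bhlhe41, Dbp and the kinase Csnk1d (slopes −0.36, −0.24 and −0.14; edgeR adjusted p = 0.0354, 0.037 and 0.0187), and 1 rise, Clock itself (0.06, adjusted p = 0.0408; −0.025 with the deposited divisors). The repressor Bhlhe40 stood at 14.4% of untreated at 6 h (adjusted p = 0.0646). Of 17 measured members 3 fell and 1 rose, also adjusted over the list alone, and the median slope of −0.14 lay at percentile 2.10. The percentile was 34.4 at a mean CPM of at least 5, 16.4 without the untreated and 2.54 without the 2 h library. With the deposited divisors 8 fell, and with respiratory chain scaling 1. Clock passed only with the 2, 4 and 6 h libraries all present, and falls numbered 6, 0 and 9 without the 2, 4 and 6 h library.

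Interferon-related mRNAs as a list did not stand apart. The antiviral Oasl1 fell to 22.6% of untreated (slope −0.35 ± 0.03, edgeR adjusted p = 0.0151), and the interferon regulatory factors Irf2, Irf5, Irf8 and Irf9 fell with slopes from −0.11 to −0.29. Of 24 measured members 5 fell and 0 rose (4 and 0 adjusted over the list alone), with a median slope of −0.044 at percentile 29.0, with 11 falls under the deposited divisors and 2 without the 4 h library, and 1 member rose without the untreated library. Of 26 apoptosis regulators 2 fell, the signalling adaptor Bcl10 (25.8% of untreated at 6 h, adjusted p = 0.0162) and the BH3 protein Bid (slope −0.20, adjusted p = 0.0145). None rose by edgeR, the same counts were obtained adjusted over the list alone, and the median slope of 0.016 (percentile 81.0) turned to −0.070 with the deposited divisors, under which 14 fell. Apoptosis calls numbered 4 falls without the untreated library, 5 falls and 1 rise without the 2 h library and 6 falls and 1 rise without the 6 h library.

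**Figure D2:**
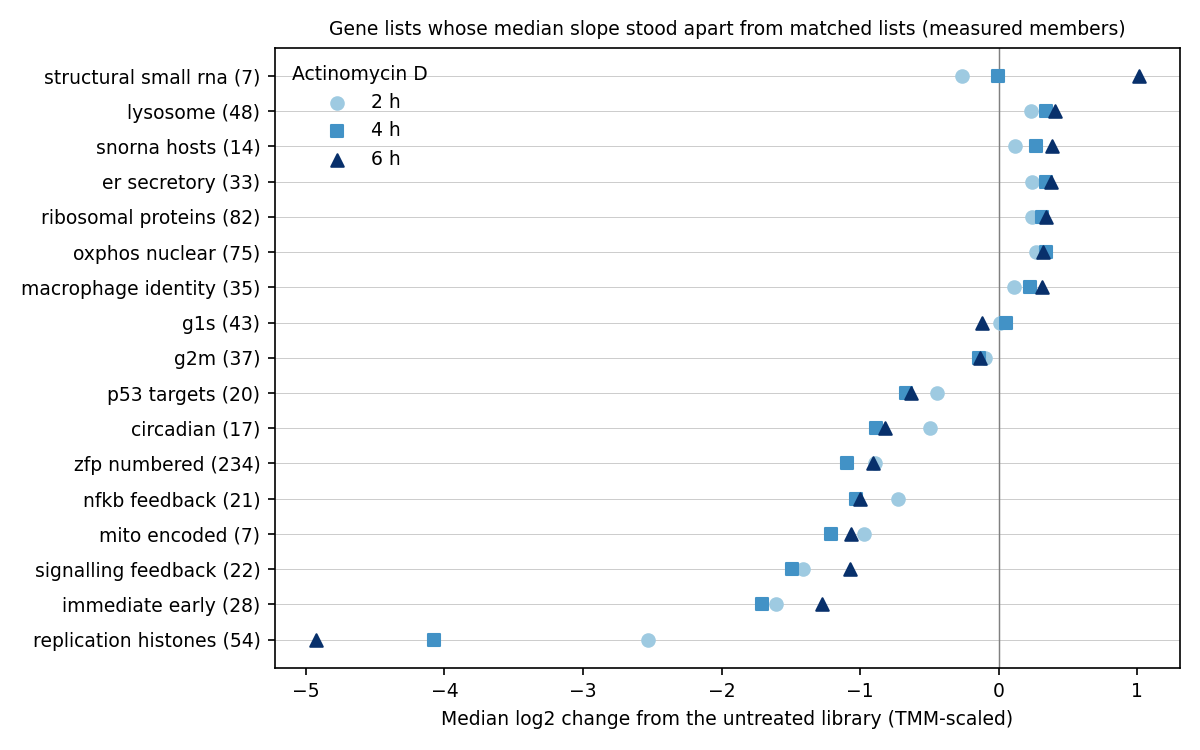
Median log2 change from the untreated library at 2, 4 and 6 h of actinomycin D, after TMM scaling, for the 17 gene lists whose median slope lay outside the central 95% of expression-matched random lists. Points are medians over list members in 1 library per time; the histone median reached −4.93 at 6 h, the lysosomal median 0.40, and the lists with medians above 0, structural small RNAs aside, had median slopes below 0 with the deposited divisors, while both cell-cycle lists had medians above 0 with total counts.

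The macrophage product lysozyme, Lyz2, rose to 187% of untreated at 6 h (counting interval 185 to 190%, slope 0.15 ± 0.02 log2 per h, edgeR adjusted p = 0.0174), and the lysosomal proteases Ctsb, Ctsd, Ctsl and Ctsh rose with slopes from 0.12 to 0.23. Lyz2 lies on chromosome 10 from 117277331 to 117282321 on the minus strand, and Ctsb on chromosome 14 from 63122462 to 63145923 on the plus strand. Against these, Tfeb and Mitf, the transcription factors that drive lysosomal genes, fell (slopes −0.35 and −0.20, adjusted p = 0.0149 and 0.0433). The pattern-recognition receptor Tlr2, on chromosome 3 from 83836272 to 83841767 on the minus strand, fell to 12.3% of untreated (counting interval 11.05 to 13.7%, slope −0.51 ± 0.06, adjusted p = 0.0188), and so did the macrophage transcription factors Cebpb and Spi1. The growth-factor receptor Csf1r was at 113% (adjusted p = 0.145).

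Of 48 measured lysosomal genes 24 rose and 2 fell (34 and 2 adjusted over the list alone), and of 35 macrophage identity genes 11 rose and 7 fell (16 and 8 adjusted over the list alone). Their median slopes of 0.065 and 0.050 lay at percentiles 100 and 98.6, and turned to −0.022 and −0.036 with the deposited divisors. Lysosomal and macrophage rises numbered 1 and 1 with total counts and 1 and 2 with the deposited divisors. Lysosomal rises numbered 16, 15, 1 and 26 without the 0, 2, 4 and 6 h library in turn, and macrophage rises 7, 5, 0 and 4, with 1 lysosomal and 3 macrophage falls without the 4 h library. The macrophage percentile was 59.6 from 0 to 2 h alone, 88.6 without the 6 h library and 94.1 at a mean CPM of at least 5. Ctsb and Lyz2 missed the test without the 4 h library, and Ctsb with the deposited divisors (edgeR adjusted p = 0.121).

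Genes of the secretory pathway in the endoplasmic reticulum, which translocate, glycosylate and fold new proteins, lay on the slow side as a group. The signal peptidase subunits Spcs1 and Spcs3, the translocon genes Ssr1, Ssr3 and Sec61a1, the folding genes Canx, Pdia3 and Pdia6 and the glycosylation subunit Rpn2 rose, with Spcs1 at 0.12 and Ssr3 at 0.11 log2 per h. The chaperone Hspa5 stood at 80.8% of untreated at 6 h (edgeR adjusted p = 0.0822). Of 33 measured members 9 rose and 0 fell (22 and 1 adjusted over the list alone). The median slope of 0.063 (percentile 99.9) turned to −0.023 with the deposited divisors, under which 10 fell and 0 rose, and 0 rose with total counts. Rises numbered 4, 4, 0 and 23 without the 0, 2, 4 and 6 h library in turn.

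Respiratory chain and ribosomal protein mRNAs, both abundant, moved to the slow side together, with median changes of 0.27, 0.34 and 0.32 log2 and of 0.24, 0.32 and 0.34 log2 at 2, 4 and 6 h. The joint test gave 2 lower and 63 higher respiratory chain genes, and 0 lower and 74 higher ribosomal protein genes. Among all 10837 genes it gave 3994 lower and 3554 higher. Among 75 nuclear-encoded respiratory chain genes 3 rose, Cox7c, Cox6c and Atp5g3 (edgeR adjusted p = 0.0462, 0.0498 and 0.0448), 0 fell, and 0 passed adjusted over the list alone. Of 82 ribosomal protein genes 15 rose and 0 fell, and 0 passed adjusted over the list alone; Rpl4 stood at 131% of untreated at 6 h (adjusted p = 0.138) and Rplp1 at 120% (adjusted p = 0.0885). Median slopes of 0.050 and 0.057 (percentiles 100 and 98.4) turned to −0.036 and −0.030 with the deposited divisors, under which 20 and 24 fell and 0 rose. Matched lists had median slopes of 0.022 and 0.047, so the ribosomal protein median lay little above that of its matched lists. Those lists could hold ribosomal protein genes themselves, which draws the 2 medians together. With total counts 0 respiratory chain and 1 ribosomal protein gene rose. Percentiles without the untreated library were 86.0 and 94.1, with total counts the ribosomal protein percentile was 97.3, and ribosomal protein rises numbered 4, 6, 0 and 33 without the 0, 2, 4 and 6 h library in turn. Respiratory chain rises numbered 0, 8, 0 and 29 in the same order. Many ribosomal protein genes have processed pseudogenes that could share their reads, so their single values are uncertain.

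Translation factors, proteasome subunits and glycolytic enzymes did not stand apart from matched lists. The initiation factor subunit Eif3a fell to 65.2% of untreated (edgeR adjusted p = 0.0185), the proteasome subunit Psmd7 to 73.8% (adjusted p = 0.0293), and hexokinase Hk2, the entry enzyme of glycolysis, to 35.8% (adjusted p = 0.0321). The glucose transporter Slc2a1 and the lactate exporter Slc16a3 also fell (slopes −0.16 and −0.14), Hk3 rose (0.10, adjusted p = 0.0401), and the elongation factor Eef1a1 stood at 127% (adjusted p = 0.172). Of 41 translation factors 2 fell and 5 rose (2 and 2 adjusted over the list alone), with a median slope of 0.042 at percentile 36.4. The proteasome had 1 fall and 0 rises among 37 members (0 and 0 adjusted over the list alone) at percentile 89.3, and glycolysis 3 falls and 1 rise among 24, also adjusted over the list alone, at percentile 6.85. All 3 medians turned negative with the deposited divisors (−0.045, −0.044 and −0.067), with 24, 20 and 17 falls. From 0 to 2 h alone the proteasome percentile was 99.86. Without the 6 h library it was 99.8, 17 proteasome and 17 translation genes rose, and without the 4 h library none of the 3 lists had a gene past the test. Translation falls numbered 5 without the untreated library and 1 without the 2 or the 6 h library, and translation rises 2 without the 2 h library. The proteasome fall was lost and 1 member rose without the 2 h library, and glycolysis rises numbered 0 and 3 without the 2 and 6 h library.

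In the stress responses the transcription factor Xbp1, a central regulator of the unfolded protein response, fell to 11.9% of untreated (counting interval 10.4 to 13.5%, slope −0.52 ± 0.05, edgeR adjusted p = 0.0151). It lies on chromosome 11 from 5520659 to 5525893 on the plus strand. Herpud1, Gclc and Hmox1 fell, and Edem1, which serves the disposal of misfolded proteins, rose to 154% (adjusted p = 0.0174; 0.0686 without the 4 h library and 0.353 with the deposited divisors). The constitutive chaperone Hspa8 fell along a straight course of 64.9%, 40.8% and 26.4% (slope −0.32 ± 0.01, adjusted p = 0.0145), and the co-chaperones Dnajb1, Bag3 and Dnaja1 fell with it. Of 28 stress genes 4 fell and 1 rose (3 and 1 adjusted over the list alone), with a median slope of −0.010 at percentile 6.23 that turned to 0.011 with total counts and was at percentile 0.610 without the 6 h library. Of 17 heat-shock genes 4 fell and 0 rose, also adjusted over the list alone, with a median of 0.014 at percentile 12.4 that turned to −0.073 with the deposited divisors, under which 11 stress and 11 heat-shock genes fell and 0 rose. From 0 to 2 h alone the stress list lay at percentile 0.160. Falls in the stress list numbered 8, 1 and 7 without the 2, 4 and 6 h library and rises 3, 0 and 6 without the 0, 4 and 6 h library; of the heat-shock list 1 gene fell without the 4 h and 4 rose without the 6 h library. Xbp1 and Hspa8 each passed whichever library was left out.

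In cholesterol metabolism the fatty acid synthase Fasn fell to 65.1% of untreated (edgeR adjusted p = 0.0287). The synthesis enzymes Sqle, Fdft1 and Hmgcs1 fell, whereas Idi1, Hsd17b7, Sc5d and Lss of the same pathway rose. Of 33 measured members 7 fell and 7 rose, also adjusted over the list alone, but 3 fell and 0 rose with total counts, 8 and 0 with ribosomal protein scaling, 5 and 0 with respiratory chain scaling and 20 and 0 with the deposited divisors. The median slope of 0.0095 lay at percentile 15.7 and turned to −0.078 with the deposited divisors, and without the 2 h library 4 fell and 2 rose, without the 4 h library 1 and 0, and without the 6 h library 4 and 5.

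Among genes of the RNA decay machinery, Ythdf1 and Ythdf2, readers of N6-methyladenosine, fell with slopes of −0.40 and −0.38 (edgeR adjusted p = 0.02 and 0.0222). The decapping genes Edc3 and Dcp1a and the deadenylase subunit Cnot2 also fell, while the decapping enzyme Dcp2, the deadenylase Cnot7, the mRNA-binding Elavl1 and Rc3h2 rose. Of 47 measured members 10 fell and 4 rose (12 and 9 adjusted over the list alone). Their median slope of 0.018 lay at percentile 47.3 and turned to −0.068 with the deposited divisors, under which 27 fell and 0 rose, and without the 4 h library 4 fell and 0 rose.

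The steepest rises picked by the fixed rule were non-coding RNAs apart from Car2, a carbonic anhydrase. Car2, on chromosome 3 from 14886273 to 14900770 on the plus strand, rose to 335% of untreated (slope 0.29 ± 0.03, edgeR adjusted p = 0.0174). The small nucleolar RNA Snora23 rose to 711% (0.50 ± 0.08, adjusted p = 0.0242), and the mitochondrial ribosomal RNAs, whose counts also depend on how far each library was depleted, rose: mt-Rnr2 to 733% and mt-Rnr1 to 664% (adjusted p = 0.0311 and 0.0213). Scarna13, Scarna2, Snord17 and Snora74a, guides of RNA modification, rose with slopes from 0.28 to 0.29. In classes chosen after the result was seen, 59 of 60 small nucleolar RNAs were higher at 6 h than at 4 h (median step 1.15 log2). All 10 Cajal body RNAs were higher too (0.75). The 4 to 6 h part of these single rises was not told apart from that shift of the class. The material is labelled as cytoplasmic RNA, and how much nuclear RNA each library held was not measured. Without the 6 h library the slopes were 0.45 for Snora23, 0.13 for Scarna13, 0.27 for Scarna2, 0.21 for Snord17 and 0.18 for Snora74a. Snora23 missed the test without the 4 h (adjusted p = 0.054) or the 6 h library (0.0509), mt-Rnr2 without the 2 h (0.114) or the 4 h library (0.118) and by the DESeq2 Wald test (0.198), and Scarna13 without the 6 h library (0.0613). With the deposited divisors Scarna13 and Snora74a missed the test (0.0897 and 0.0611).

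Host transcripts of small nucleolar RNAs rose in 4 of 14 cases, Snhg1, Snhg8, Snhg17 and Snhg20, and none fell by edgeR (5 rose and 1 fell adjusted over the list alone). Their median slope of 0.065 (percentile 99.97) turned to −0.023 with the deposited divisors, and 0 rose with those or without the 4 or the 6 h library. Rises numbered 7 and 2 without the 0 and 2 h library, and 1 member fell without the 2 or the 6 h library. Structural small RNAs, such as the RNA components of RNase P (Rpph1) and RNase MRP (Rmrp) and the 7SK RNA (Rn7sk), had median changes of −0.27 log2 at 2 h, −0.0053 at 4 h and 1.01 at 6 h. Rpph1 stood at 207% and Rn7sk at 183% of untreated at 6 h (adjusted p = 0.0943 and 0.099). Of 7 measured members 1 rose, the telomerase RNA Terc (0.19, adjusted p = 0.0279), and 0 fell, also adjusted over the list alone, and with the deposited divisors 0 rose. Their median slope of 0.18 was above 0 under all 7 scalings and at percentile 100, but was −0.041 against matched lists without the 6 h library (percentile 15.0) and −0.40 from 0 to 2 h alone (percentile 0.780). Members that rose numbered 6 without the untreated library and 0 without the 4 h library.

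Of 8 nuclear-retained long non-coding RNAs 2 fell, the paraspeckle scaffold Neat1 (47.4% of untreated at 6 h, edgeR adjusted p = 0.0372) and the imprinted antisense RNA Kcnq1ot1 (59.6%, adjusted p = 0.0386), and 0 rose, also adjusted over the list alone. The abundant Malat1 stood at 235%, 257% and 305% (adjusted p = 0.0664). The list's median slope of 0.019 (percentile 60.0) turned to −0.068 with the deposited divisors, 0 passed with total counts or without the 4 h library, and 1 rose without the 2 h library. Counting is not stated to use strand, so antisense RNAs and their partners could share reads. The labels name cytoplasmic RNA, so these levels also depend on how much nuclear RNA each library held, which was not measured.

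Of 7 measured protein mRNAs encoded on the mitochondrial genome, mt-Nd1 and mt-Cytb, subunits of complexes I and III, fell to 21.8% and 32.6% of untreated (edgeR adjusted p = 0.016 and 0.0222), whereas mt-Co1 stood at 111%, 167% and 157% (adjusted p = 0.0563). No member rose by edgeR, and adjusted over the list alone 2 fell and 1 rose. The median slope of −0.17 lay below all matched lists, but without the untreated library it lay 0.078 above them (percentile 100), with 4 members rising. Falls numbered 5, 1 and 3 without the 2, 4 and 6 h library, and 1 member rose without the 6 h library. Of the markers of other cell types 3 were measured, Dcstamp and Acp5 of osteoclasts and Cd79b of B cells. None of the 3 passed the trend test by edgeR or adjusted over the list alone, and the median slope of 0.015 (percentile 69.7) turned to −0.073 with the deposited divisors, under which 1 fell.

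Many courses bent, and with TMM scaling more bent upward than downward, nearly all upward ones standing below the untreated level at 2 h. Rasgef1b, an exchange factor for Ras-family proteins, and Ppp1r10, a nuclear phosphatase regulator, stood at 8.13% and 9.27% of untreated at 2 h and at 9.38% and 7.64% at 6 h. The largest bends of the fixed rule also included Nfkbia and the clone-named genes RP23-81C12.3 and RP23-81C12.1, which stood at 0.919% and 1.26% at 2 h and 2.47% and 0.862% at 6 h. By edgeR's test of the quadratic term, 2056 genes bent upward and 1312 downward at an adjusted p under 0.05, and 4670 had an unadjusted p under 0.05. Genes with an upward bend changed by a median of −0.90 log2 from 0 to 2 h, −0.25 from 2 to 4 h and 0.12 from 4 to 6 h, and 2026 of them were lower at 2 h than untreated. Of them 632 were lower at 6 h than at 4 h, 719 also fell on the straight line, and 29 rose. Genes with a downward bend had median steps of 0.27, 0.094 and −0.060, with 1269 above the untreated level at 2 h. The deposited divisors gave 3320 upward and 71 downward bends.

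Histone mRNAs were among the RNAs with the shortest half-lives, and most measured genes had values beyond the length of the course. The clone-named gene RP23-81C12.1 had a value of 0.842 h, which does not describe its bent course of an early loss and a flat remainder. It missed the line test (edgeR adjusted p = 0.0611), and its slope of −1.13 was −0.14 without the untreated library. With the median ribosomal protein mRNA taken as not decaying, the apparent half-life was 0.720 h for Hist1h3h, 1.72 h for Xbp1, 1.76 h for Tlr2, 2.30 h for Tigar and 2.64 h for Hspa8. The median over 10837 genes was 18.1 h (quartiles 6.33 and 190 h), with 160 genes under 2 h and 2420 not falling against the anchor. With this anchor, any decay of ribosomal protein mRNAs makes the values too long. The anchor, times and scaling set this scale: the median was 8.69 h with 1434 genes under 2 h from 0 to 2 h alone, 12.1 h with the 90th percentile of slopes and 20.4 h with respiratory chain mRNAs as anchor, and 11.7 h with the deposited divisors. It was 32.9 h with 70 genes under 2 h without the untreated library, and without the 6 h library 13.3 h with 689 under 2 h.

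In the authors' deposited table the median half-life of 10836 of these genes was 8.56 h (quartiles 3.78 and 21.2 h), 1003 were under 2 h and 988 were negative. All 14957 half-lives in the authors' deposited table matched, within a relative tolerance of 1e-06, a line through the origin over the log ratios at 0, 2 and 4 h, and 0 matched a line that included 6 h. A 4-point line through the same normalized values had a free intercept, so it differed from the deposited fit in the intercept as well as in the added 6 h library. The parts of these 2 changes were not told apart. This line gave a median of 11.7 h and 182 genes under 2 h, against 1002 in the authors' deposited table for the genes compared. Of those 1002, 251 were over 3 h or not falling with 4 points. Across genes, decay rates from the authors' deposited table and from the 4-point line had a rank correlation of 0.916, a description of genes that are not independent replicates. The authors' deposited table lists 0.628 h for Hist1h3h, 1.13 h for Fos, 1.15 h for Tnf, 1.55 h for Mcl1, 1.29 h for Xbp1 and 1.24 h for Tlr2.

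**Figure D3:**
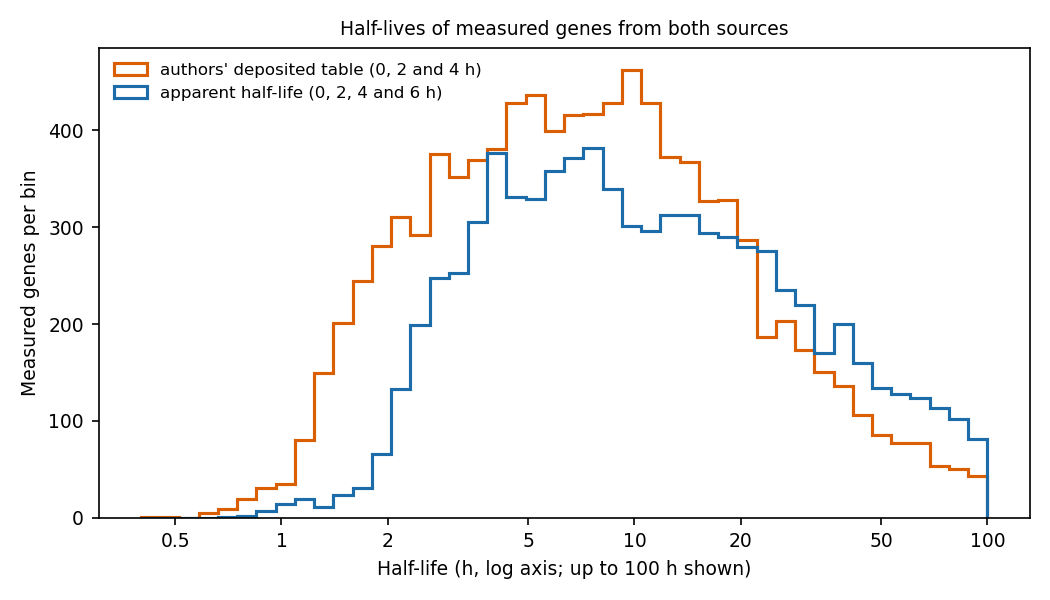
Number of genes by half-life in hours, on a log axis up to 100 h, for the half-lives in the authors' deposited table and for the apparent half-lives computed from 4 time points against ribosomal protein mRNAs. The deposited half-lives had a median of 8.56 h and the apparent ones of 18.1 h over the measured genes, negative or not falling values left out of the bars.

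Genes whose 3' UTR holds the nonamer TTATTTA(A/T)(A/T), the core of AU-rich elements that recruit decay factors, did not stand apart on the measure fixed in advance. The 1531 such genes had a median slope of −0.015 log2 per h against −0.0095 in lists matched on expression and 3' UTR length, at percentile 4.07, and 17.6% of them fell against 17.9% of genes without it. The alternative fixed in advance, at least 3 ATTTA pentamers (3324 genes), lay 0.0046 above its matched lists, at percentile 99.86. Matched lists could hold motif genes themselves, so these differences and percentiles do not compare genes with and without the motif. Without matching, genes lacking the nonamer had a median slope of 0.0021. The median was −0.0035 for the pentamer genes and 0.0019 for genes without 3 pentamers. In all, 6 combinations of motif and measure were computed, 4 of them chosen after the values were seen. Among these 4 the 0 to 2 h change of the nonamer genes lay at percentile 0.170, by −0.030 log2, that of 342 genes with at least 2 nonamers at 0.980, by −0.065, and that of the pentamer genes at 99.99, by 0.018. The slope of genes with at least 2 nonamers lay at percentile 25.7. Across genes, which are not independent replicates, Spearman's rho with the slope was −0.084 for GC content at the last codon position, −0.056 for 3' UTR length and −0.19 for coding length, and with the 0 to 2 h change it was −0.18, −0.11 and −0.22, among 10 such relations computed.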

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

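The deposited divisors, total counts without 4 genes, the joint test, the through-origin half-lives and the 0 to 2 h, 2-nonamer and 0 to 2 h pentamer measures of the 3' UTR were chosen after the results were seen; other alternatives were fixed before the data were examined, and the cause of a changed result was not tested unless the setting's construction shows it. No paired analysis was possible because each time point has 1 library. Of 17 alternatives, 14 kept the count of falls and 7 the count of rises within 1.5 times. Rises numbered 207 with total counts, 131 with ribosomal protein scaling, 61 with respiratory chain scaling, 561 with no filter, 334 with total counts without 4 genes and 1529 with the DESeq2 Wald test. The joint test gave 3994 lower and 3554 higher genes, and the deposited divisors 5039 falls, 78 rises, 3320 upward and 71 downward bends. Median half-lives were 12.1 h with the 90th percentile anchor, 8.69 h (1434 genes under 2 h) from 0 to 2 h only, 11.7 h with the deposited divisors and 11.9 h (863 genes) through the origin over 2 and 4 h, and 103 genes were under 2 h with least squares on log2 values. Without an anchor the median gene did not fall and gave no finite half-life. Of 231 alternatives for gene lists 203 kept the call, 6 reversed, 17 moved inside the central range and 5 moved out of it. Total counts and the deposited divisors, which are among them, shift all slopes by nearly the same amount. They could therefore hardly move a list against its matched lists, and the calls kept under them say little on scaling. The values, as list medians against matched lists, follow. The 0 to 2 h change gave −0.56 for cytokines, −0.090 for G1/S genes, 0.11 for the proteasome, 0.010 for macrophage identity, −0.23 for stress genes, 0.27 for snoRNA hosts and −0.40 for structural small RNAs. A mean CPM of at least 5 gave −0.063 for p53 targets, 0.017 for macrophage identity and −0.024 for clock genes, and total counts 0.0091 for ribosomal proteins. Of 2395 alternatives for slopes of 141 named genes, 2021 kept the call, 136 lost it, 209 gained it and 29 reversed. A reversal was counted only where the slope passed the test in either fit, so the 2021 include slopes whose sign turned without a pass. Deposited divisors, which lower the slopes of named genes, reversed Gapdh (−0.027), B2m (−0.0040), Nfkb1 (−0.079), Cyld (−0.071), Bax (−0.053), Bak1 (−0.058), Xiap (−0.043), Bub1b (−0.073), Rpl8 (−0.039), Pkm (−0.049), Ldha (−0.047), Aldoa (−0.045), Csf1r (−0.057), Psap (−0.031), Txnrd1 (−0.060), Hsp90ab1 (−0.056), Scd2 (−0.046), Srebf2 (−0.059), Clock (−0.025), Khsrp (−0.047) and Zfp106 (−0.020). The joint test, whose direction is the mean of the treated libraries against the untreated one, reversed Srf (−0.078), Mcm5 (0.017), Cnot1 (0.082) and Dcstamp (−0.015). Changes of benchmark genes, 24 values, were computed again with total counts and with a prior count of 2, and kept their size in 26 of these 48 alternatives. All 22 that moved did so with total counts, and none with the prior count of 2. With total counts they were −2.32 and −2.10 for Fos at 2 and 4 h, −0.69, −0.57 and −0.12 for Ier2 at 2, 4 and 6 h, −2.20 and −2.11 for Tnf at 2 and 4 h, −1.13, −1.52 and −1.45 for Mcl1, −0.20, −0.41 and −0.52 for Cdkn1a, 0.62, 0.68 and 0.52 for Gapdh, 0.49, 0.65 and 0.62 for Actb, and 0.76, 0.80 and 0.68 for B2m at 2, 4 and 6 h. For the 3' UTR, at least 3 ATTTA pentamers gave 0.0046, the 0 to 2 h change −0.030, the same with at least 2 nonamers −0.065 and with pentamers 0.018. Leaving out each library in turn gave 351 to 2242 falls, 25 to 1141 rises, median half-lives of 13.3 to 32.9 h and 70 to 689 genes under 2 h. List medians against matched lists then ranged from −0.39 to 0.084 for immediate-early genes, −0.33 to 0.051 for signalling feedback, −0.066 to 0.19 for cytokines, −0.23 to −0.050 for NF-kB, −0.14 to −0.0013 for p53 targets, −0.076 to −0.015 for mitotic genes, −0.046 to −0.026 for G1/S genes, 0.0061 to 0.012 for ribosomal proteins, 0.0067 to 0.051 for the respiratory chain, −0.36 to 0.078 for mitochondrially encoded mRNAs, −0.0080 to 0.035 for the proteasome, 0.018 to 0.028 for macrophage identity, −0.074 to 0.013 for stress genes, −0.18 to −0.031 for clock genes, −0.041 to 0.29 for structural small RNAs and −0.23 to −0.00086 for numbered Zfp genes. Slopes ranged from −0.61 to 0.22 for Fos, −0.23 to 0.20 for Ier2, −0.61 to 0.19 for Tnf and −1.85 to 0.36 for RP23-81C12.3. Depth limits the 6 h values most, since that library held 12762100 counts.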

Other observations

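The classes of non-coding RNA in the next paragraph and all tests of this part were chosen after the patterns they address were seen. Only for the test of GC content and transcript length was the prediction written before that test's own value was seen.

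From 4 to 6 h nearly all measured short non-coding RNAs stood higher relative to the typical gene, which TMM scaling sets near 0. Of 60 measured small nucleolar RNAs, which guide the modification of ribosomal RNA, 59 were higher at 6 h than at 4 h, with a median step of 1.15 log2. All 10 measured Cajal body RNAs were higher (median step 0.75), as were all 7 spliceosomal small nuclear RNAs (1.02). Long intergenic RNAs were higher in 20 of 28 cases (0.20) and antisense RNAs in 19 of 26 (0.27). By length, 84 of 86 non-coding RNAs of at most 350 nt were higher (1.01), against 58 of 86 over 1000 nt (0.15) and 90 of 172 coding transcripts of 350 to 700 nt, histones left out (0.0044). These steps compare 2 libraries with no replicate, and 4748 of 9772 coding genes were higher over the same step.

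Immediate-early mRNAs were higher at 6 h than at 4 h in 23 of 28 cases, by a median of 0.28 log2 (interquartile range 0.49), against −0.0021 for all genes. Carry-over of untreated RNA into the 6 h library would have to add 9.65% of the untreated level to the list, but the histone mRNAs were left at a median of 3.29% at 6 h (interquartile range 2.28), which argues against it. Bias from GC content and transcript length is argued against as well, since the list lay at percentile 100 of 10000 lists matched on both, of which the highest reached 0.16. More nuclear RNA in the 6 h library stays open: the 8 nuclear-retained RNAs had a median step of 0.13 (interquartile range 0.22), which overlaps that of the list. Levels here are relative to the typical gene, so late decay slower than that of the typical gene may also contribute, though slower decay cannot raise an absolute level. Incomplete shut-off may contribute too, and no biological explanation was tested.

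Structural small RNAs were higher at 6 h than at 4 h in 7 of 7 cases, by a median of 0.88 log2 (0.70 to 1.15). A preference for short RNAs in the 6 h library could give this, and stays open. More nuclear RNA in that library was not tested on these RNAs and stays open as well. The shortest decile of coding transcripts, 978 genes of up to 1229 nt, stepped by −0.0187 log2 against the rest, but 0 coding transcripts outside the histones were as short as the list's median RNA of 290 nt, the shortest having 345 nt. The requirement that coding transcripts of that length be present was set, and once revised, after the value was seen. No biological explanation was tested.

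The order of the 4 libraries along the time axis can be changed in 12 distinct ways, of which 1, the real one, gave as many genes past the trend. The real order gave 2794 genes and the highest other order 0 by edgeR, with up to 3191 at an unadjusted p under 0.05 in the other orders. These orders are too few for a share under 0.05.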
